A study of Mus musculus with 6 samples.

How the data were processed

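Total RNA (8 ug per sample) from mouse dendritic cells was measured on 6 Affymetrix MOE430A arrays, 1 array for each of 6 groups. Per the labels, the cells came from bone marrow of CAR-transgenic mice, were expanded for 7 days and then differentiated for 7 days with 250 U/ml GM-CSF. They were transduced with the adenovirus AdIkBa-SR or the control virus AdOVA at 1500 particles per cell, or left without virus, and each of these 3 virus states was measured without and with TNFa. Groups were taken from the sample titles, and every array column of the deposited table was matched to 1 sample by its name.

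The values are microarray intensity on a linear scale, deposited by the authors as 1 signal per probe set, and made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. MAS5 sets each array to a common average signal. The 2% trimmed mean was 200.1 on every array, and the largest was 1.0001 times the smallest, so the deposited signals were used without rescaling (a ratio above 1.05 would have led to it). The table holds 22690 probe sets, of which 64 are controls. Of the other 22626, the platform annotation gives 1 gene symbol to 20380, several to 691 and none to 1555. The 20380 probe sets name 12393 genes, and no gene was named from a probe set with several symbols. The scanner and fluidics settings of each array were read from the array headers. The untreated, TNFa and AdOVA arrays share 1 recorded hybridization date and the other arrays share another. These dates are called fluidics rounds 1 and 2 here, so a round can also carry differences in hybridization. The AdIkBa-SR array was washed with another protocol, with 0 cycles in both recorded washes and 420 s in the first stain, where the other arrays had 10 and 4 cycles and 600 s.

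Signals under a floor of 53.5, the 40th percentile of all non-control signals, were set to the floor and log2 values taken. A fold with 1 array under the floor is a bound and is written as "at least". A probe set counted as measured when it was above the floor on at least 2 arrays, which left 14906. A gene was read from its brightest probe set with 1 symbol. MAS5 signals near the floor are noisy, so log2 differences of dim genes are both less precise and compressed by the floor.

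With 1 array per group, the primary comparisons carry no p-value. For each factor, probe sets were counted that were at least 2-fold apart in the same direction in 2 pairs of arrays that share no array. For TNFa these were TNFa over untreated and AdOVA+TNFa over AdOVA. For AdOVA they were AdOVA over untreated and AdOVA+TNFa over TNFa. For AdIkBa-SR they were AdIkBa-SR over AdOVA and AdIkBa-SR+TNFa over AdOVA+TNFa. Beside each count stands the number that independent lists would share (the product of both counts divided by the number of probe sets that could pass in both). In addition, limma (lmFit, then eBayes with a trend on mean signal) was fitted to all 6 arrays with 5 coefficients, which leaves 1 residual degree of freedom. The 5 coefficients are 3 virus states, 1 TNFa response shared by cells without virus and with AdOVA, and 1 TNFa response in AdIkBa-SR cells. Its spread therefore measures how far the TNFa responses without virus and with AdOVA differ, pooled over probe sets, and the AdIkBa-SR arrays are assumed to vary like the others. Benjamini-Hochberg adjusted p-values under 0.05 were called. A log2 difference given with limma's SE or p-value is the fitted contrast. For contrasts of AdIkBa-SR with AdOVA or with no virus, it and its p-value use arrays of all 3 virus states. It can therefore differ from the pair of arrays whose signals stand beside it. In simulated data with 200 of 14906 probe sets changed by AdOVA, the fit found 0 of the 2-fold changes, 192 of the 4-fold and 199 of the 8-fold changes, with 0, 5 and 6 false calls. The changed probe sets were drawn from those above the median signal. The noise was normal, with a spread taken from the same difference in TNFa responses that the fit uses. These rates therefore do not cover dim probe sets or variation between cultures. The step for gene lists was also tested on simulated data.

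Gene names were chosen by a rule written before the data were examined. For each factor it takes the 10 genes per direction with the largest value of the smaller of the 2 log2 differences, with all 4 arrays above the floor. It adds up to 5 genes per direction that are under the floor on the dim array of both pairs. For suppression by AdIkBa-SR it takes the 10 genes with the largest fall from the TNFa response in AdOVA cells to that in AdIkBa-SR cells, among those at least 2-fold higher with TNFa without virus. It also takes Nfkbia and members of 20 gene lists: NF-kB pathway, cytokines, chemokines, DC maturation, uptake receptors of immature DC, interferon-stimulated genes, survival, MHC class I processing, proliferation, stress and death, cholesterol synthesis, reference genes, and 8 lists of markers of T, B, NK, granulocyte, mast cell or basophil, erythroid, macrophage and stromal cells. Of 263 listed genes, 215 were measured, 24 were under the floor on all arrays or all but 1, 1 (Gapdh) has control probe sets only and 23 were not analysed here. Each list's median log2 difference was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. Its spread in the alternatives was estimated from 1000 bootstrap draws over genes.

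The alternatives tried were equal medians and quantile normalization as other scalings, floors at the 25th and 60th percentiles, a pseudocount of the floor value in place of the floor, 1.5-fold and 3-fold thresholds, and leaving out the 2981 probe sets that can read several genes. For limma they were also no trend, no filter and additive fits of 6 or 4 arrays, and for genes the mean over all probe sets. The fluidics round as a block, fits without the AdOVA+TNFa or the AdIkBa-SR array, the comparison of AdIkBa-SR with untreated cells and the groups of ribosomal and respiratory chain genes were chosen after seeing the data. The fits with the round as a block and without the AdOVA+TNFa array were additive, with 1 TNFa response for all virus states. AdOVA+TNFa over AdOVA is the only pair within a virus state that spans both rounds. The round term therefore takes up the AdOVA+TNFa array, so these fits are not separate checks and cannot tell the round from that array. Their spread comes only from how far the TNFa responses without virus and with AdIkBa-SR differ, the latter across different wash settings. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.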

Results

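Gene expression was measured in mouse dendritic cells (DC), which take up antigen and present it to T cells, grown in culture from bone marrow. The cells were left without virus, transduced with the adenovirus AdIkBa-SR or transduced with AdOVA, the control adenovirus. IkBa holds the transcription factor NF-kB in the cytoplasm, and its super-repressor (SR) form resists the breakdown that normally releases NF-kB. Virus was given for 2 h and followed by 18 h of culture, after which TNFa, a cytokine that activates NF-kB, was added at 50 ng/ml for 4 h or left out. Each of the 6 resulting groups (untreated, TNFa, AdOVA, AdOVA+TNFa, AdIkBa-SR and AdIkBa-SR+TNFa) has 1 Affymetrix MOE430A array. The median signal ran from 74.4 on the AdIkBa-SR array to 88.5 on the AdOVA+TNFa array, and the share of probe sets above the floor of 53.5 from 57.9% to 63.4%. No difference between single arrays has a replicate check, the labels do not say that the groups came from separate cultures, and the number of arrays limits the precision. The p-values given are limma's, from 1 fit of all 6 arrays with 1 residual degree of freedom.

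Nfkbia, the gene of IkBa, is read by 4 probe sets, and whether any of them reads the viral transgene is not known, so its level checks nothing about delivery. The brightest probe set had signals of 10622 untreated, 10697 with TNFa, 16336 with AdOVA, 9729 with AdOVA+TNFa, 10118 with AdIkBa-SR and 8571 with AdIkBa-SR+TNFa. On another probe set the signals were 1981, 2044, 5338, 5066, 1849 and 2997 in the same order, a rise with AdOVA (log2 1.37, limma adjusted p = 0.0035). AdIkBa-SR lowered that probe set against AdOVA without TNFa (fitted log2 -1.50, adjusted p = 0.041). The other probe sets read 1837 untreated and 3147 with AdOVA, and 424 and 784. The 4 probe sets disagreed in sign for AdOVA with TNFa, where log2 differences ran from -0.14 to 1.31, and for TNFa in AdIkBa-SR cells, from -0.24 to 1.00.

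With AdOVA, the control virus, 21 of 27 measured interferon-stimulated genes and 7 of 15 chemokines rose. Cxcl10, an attractant of activated T cells, rose from a signal of 314 to 7909 without TNFa and from 330 to 7073 with TNFa (mean log2 4.54, SE 0.24, limma adjusted p = 2.3e-09). Oasl1, a member of the oligoadenylate synthetase family, rose 16.8-fold without and 16.4-fold with TNFa (adjusted p = 4.3e-09). Il6, a cytokine of the acute inflammatory response, rose from 213 to 3114 and from 326 to 2749 (log2 3.48, SE 0.26, adjusted p = 1e-07). S100a4, a calcium-binding protein linked to cell motility, fell from 1414 to 240 without TNFa and from 753 to 127 with it (log2 -2.57, SE 0.24, adjusted p = 1.9e-06). Fn1, the matrix protein fibronectin, fell from 1879 to 361 and from 2259 to 525 (log2 -2.24, SE 0.24, adjusted p = 9.9e-06).

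The comparison asks which genes the control virus regulates, and it was read in 2 pairs that share no array. No mock transduction is recorded for the arrays without virus. In every comparison with them, the virus therefore cannot be told apart from the transduction procedure and the hours of culture after it. The 10 genes with the largest rise in both pairs also include Cmpk2, a mitochondrial nucleotide kinase induced by interferon, Cxcl11, the neutrophil attractant Cxcl1, the antiviral genes Ifit1, Ifit2, Ifit3 and Mx1, all with limma adjusted p-values of 9.1e-06 or less. Ifit2 rose 9.7-fold without TNFa and 10.3-fold with TNFa, and Cxcl1 rose 10.9-fold and 9.2-fold. Among genes under the floor on both arrays without virus, the antiviral gene Mx2 rose at least 8.0-fold and at least 10.6-fold, to signals of 428 and 565. Nr5a1, Pcp4, Plagl1 and Nlgn2 rose from under the floor as well, by at least 2.9-fold in each pair. The 10 genes with the largest fall also include Cd93, a receptor of myeloid cells (650 to 117 and 427 to 112), the platelet chemokine Ppbp, the adenine nucleotide carrier Slc25a5 and the metabolic enzymes Idh1, Hadh and Gcsh. Ttc13 and Ccn3 complete these 10, with limma adjusted p-values from 1.9e-06 to 0.00094 over the set. Cks1b, a cell-cycle kinase subunit, fell at least 3.6-fold and at least 2.9-fold, and Nol12, Cdca7l, Adk and Olfm1 also fell to under the floor (adjusted p from 0.0015 to 0.0052 over the 5 genes). Averaged over all probe sets of the gene, the mean log2 difference was 1.92 in place of 3.44 for Cxcl11 and -1.17 in place of -2.20 for Cd93, and it was also smaller for Olfm1, at -1.09.

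Interferon-stimulated genes rose as a group with AdOVA: limma called 21 of 27 measured members as risen and 0 as fallen, and 24 when adjusted over the list alone. Rsad2, an antiviral enzyme, went from 2889 to 19264 without TNFa, and Gbp2, a GTPase of cell-autonomous defence, from 1425 to 8536. Zbp1, a sensor of nucleic acids (826 to 1109), was not called. Of 15 measured cytokines, 8 rose and 7 were not called (9 rose adjusted over the list alone). The interleukin-1 genes Il1a (1275 to 5839) and Il1b (3788 to 13872) and Tnf itself (139 to 598) were among the 8. Of 15 chemokines, 7 rose and 1 fell (8 and 2 adjusted over the list alone). Ccl4 rose from 525 to 3126, and Ccl17, a chemokine that attracts Th2 cells, fell from 1683 to 546 (limma adjusted p = 0.00022). In the NF-kB pathway list, 4 of 16 members rose (6 adjusted over the list alone): Tnfaip3, which encodes the NF-kB inhibitor A20, Nfkbib, Nfkbiz and Traf1. Tnfaip3 rose from 162 to 512 without TNFa and from 189 to 1462 with it (limma adjusted p = 0.00012).

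Genes of other lists also changed with AdOVA. Of 15 stress and death genes, 5 rose (7 adjusted over the list alone), with the heat-shock gene Hspa1b at 115 and 700, Hspa1a at 83.4 and 443, the cell-cycle inhibitor Cdkn1a at 1518 and 3270, and also Atf3 and Hmox1. Of 20 DC maturation genes, 3 rose (3 adjusted over the list alone): the migration receptor Ccr7, the inhibitory ligand Cd274 and Il15ra. The costimulatory genes Cd40 (79.3 and 143), Cd80 and Cd86 were not called. Of 14 MHC class I processing genes, 3 rose (3 adjusted over the list alone), namely Psmb9, Tap1 and Tap2, and of 9 survival genes, 2 rose (4 adjusted over the list alone), Gadd45b and Ier3. Of 17 proliferation genes, 3 fell: Top2a (226 to 56.2), Rrm2 and Cdk1, and adjusted over the list alone 5 fell and 1 rose. Among 16 uptake receptors, the Fc receptor Fcgr1 rose and the scavenger receptor Cd36 fell (2 rose and 3 fell adjusted over the list alone). limma called 0 of 11 cholesterol synthesis genes, 3 as fallen when adjusted over the list alone, with a median log2 of -0.78 without TNFa (percentile 0.0 of random lists). Averaged over both pairs, its median was -0.64, and -0.26 when every gene was read as the mean over all its probe sets. Of 7 reference genes, Hprt fell (875 and 748 without TNFa, 929 and 274 with TNFa, adjusted p = 0.048), and 1 fell adjusted over the list alone.

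**Figure D1:**
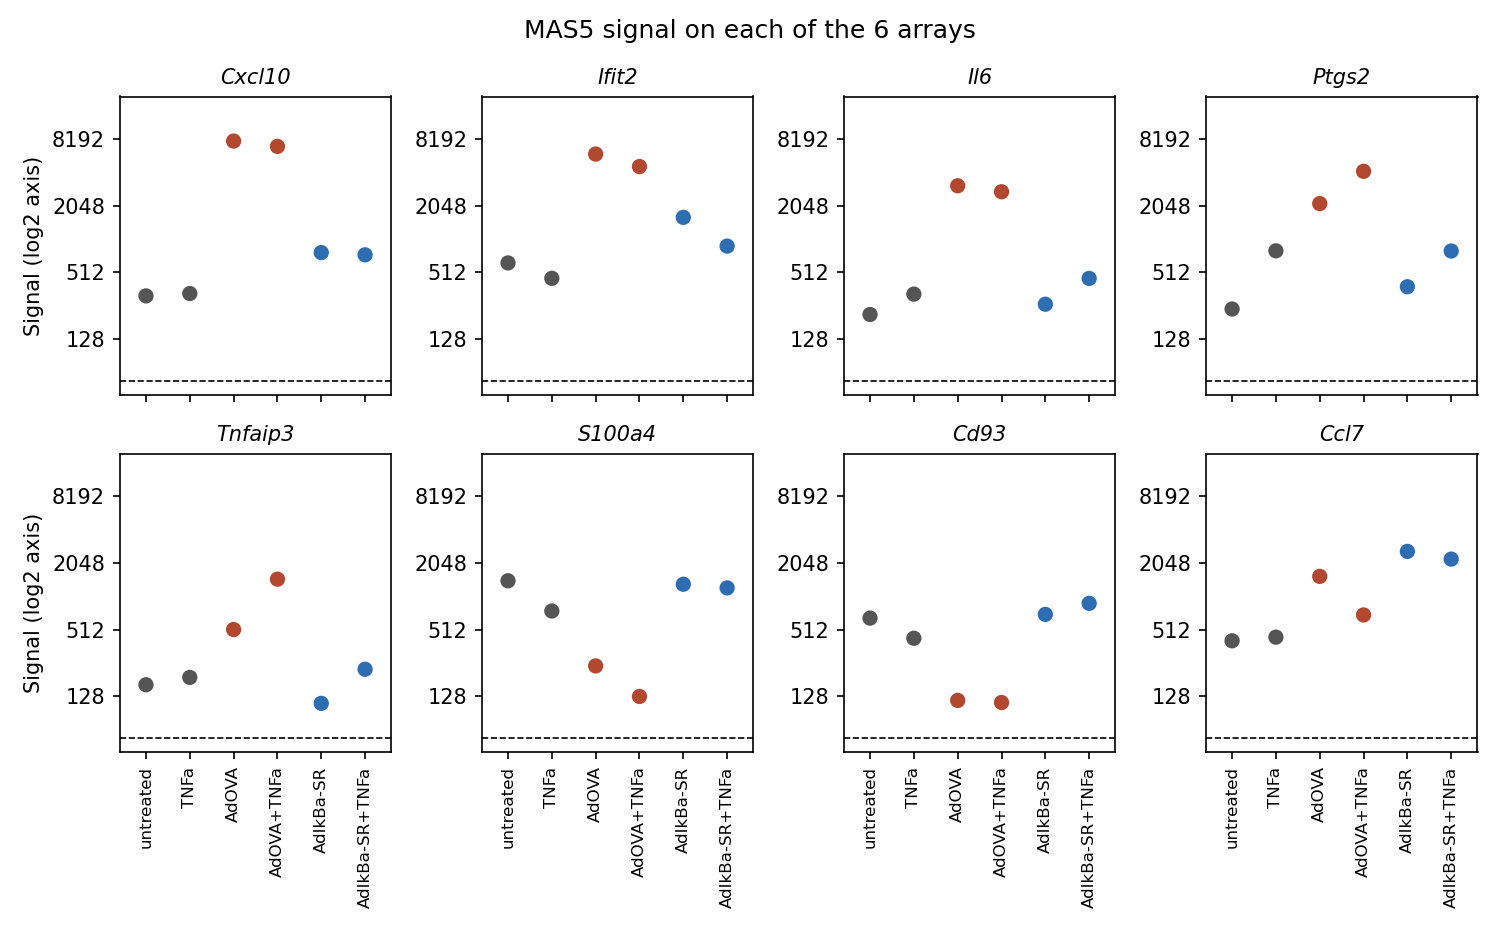
MAS5 signal (log2-scaled y axis) of 8 genes on each of the 6 arrays (x axis), with the floor of 53.5 as a dashed line; each point is 1 array. Cxcl10 stands at 7909 and 7073 on the AdOVA arrays and at 774 and 739 on the AdIkBa-SR arrays, while Ccl7 is highest on the AdIkBa-SR arrays, at 2608 and 2221.

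In total, 285 probe sets were at least 2-fold higher and 204 at least 2-fold lower with AdOVA in both pairs, where independent lists would share 41.9 and 34.0. The log2 differences of both pairs had r = 0.53 across probe sets, which are not independent replicates. limma called 600 as risen and 575 as fallen, among them 283 of the 285 and 203 of the 204. The balance of directions depends on scaling: with equal medians the pairs shared 197 higher and 336 lower and limma called 315 and 617, and with quantile normalization limma called 176 and 83. Equal medians moved the median log2 difference of all measured probe sets for AdOVA+TNFa over TNFa from 0.07 to -0.09, and for AdIkBa-SR+TNFa over AdOVA+TNFa from -0.12 to 0.06. Within fluidics round 1, AdOVA over untreated had 666 probe sets at least 2-fold higher and 665 lower. The additive fit of 6 arrays called 315 as risen and 177 as fallen. With the round as a block, that fit called 0 (2042 at an unadjusted p under 0.05), and it called none without the AdOVA+TNFa array. The latter fits are not separate checks, since the round term takes up that array, and they cannot tell the round from it.

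TNFa raised 4 probe sets beyond the spread of the fit, and each of their genes has a probe set that was not called. A probe set of Tnfrsf1b, which encodes TNF receptor 2, rose from a signal of 376 to 853 without virus and from 802 to 2984 with AdOVA (mean log2 1.54, SE 0.25, limma adjusted p = 0.04). The brighter probe set of Tnfrsf1b stood at 2358 and 3549, and at 4594 and 5394 (log2 0.41, adjusted p = 0.63). Slc20a2, a phosphate transporter, rose at least 3.3-fold without virus and at least 4.9-fold with AdOVA, to signals of 179 and 261 (adjusted p = 0.04), with both arrays without TNFa under the floor and set to it, while its other probe set had 161 and 119, and 120 and 134. A probe set each of the kinase gene Mark2 and of Mafg, a small Maf transcription factor, rose from under the floor to 179 and 182 without virus and to 251 and 214 with AdOVA (limma adjusted p = 0.04 for each). The brightest probe set had 172 and 129, and 109 and 198, for Mark2 and 396 and 384, and 536 and 598, for Mafg (adjusted p = 0.87 and 0.96). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, had signals of 239 untreated and 803 with TNFa, and 2148 and 4210 with AdOVA, and was not called for TNFa (log2 1.36, SE 0.25, adjusted p = 0.1).

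The comparison asks which genes TNFa moves up or down, without virus and with AdOVA. Tnfrsf1b, Mark2 and Mafg fall outside the naming rule, which reads a gene from its brightest probe set, and were chosen after their values were seen. Among the 10 genes with the largest higher values in both pairs were Bace1, a membrane protease (86.5 and 216 without virus, 105 and 257 with AdOVA), the protocadherin Pcdh7 (134 and 371, 132 and 317) and the chromatin remodeller Chd4 (58.4 and 116, 65.7 and 153). Rexo1, Stk10, Usp22, Rab43, Cpeb2 and Gpbp1l1 complete the set with Ptgs2, and limma called none of these 10 (adjusted p from 0.1 to 0.24). Averaged over all probe sets of the gene, log2 differences were much smaller for Bace1, Chd4, Rab43 and Slc20a2, 0.40, 0.62, 0.45 and 0.94. Speer4f1 was at least 2.3-fold and at least 3.1-fold higher and was not called.

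Of the 12 genes named for lower signals in both pairs, limma called none (adjusted p from 0.12 to 0.19). The ribosomal protein gene Rps18 stood at 4393 untreated and 2102 with TNFa, and at 2566 and 1211 with AdOVA. The complex I subunit gene Ndufa5 stood at 247 and 115, and 139 and 67.1, the mitochondrial chaperonin gene Hspe1 at 531 and 253, and 368 and 111, and Slirp, a regulator of mitochondrial RNA, at 751 and 375, and 679 and 272. The RNA helicase gene Dhx9 had 343 and 141, and 313 and 130, with a log2 difference of -0.72 over all its probe sets. Smim26, H1f10, Rnasek, Asf1b and Tmem147 were 2.0-fold to 3.0-fold lower in each pair, and Gstm7 and Elane, the neutrophil elastase gene, at least 2.3-fold. The AdOVA+TNFa array, which enters this contrast, read 2601.1 on the 5' probe set for 18S ribosomal RNA, against 233.6 on the AdOVA array, 176.2 on the TNFa array and 120.3 on the untreated array.

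No list had a member called for TNFa over all probe sets. The NF-kB pathway list had a median log2 difference of 0.28 without virus (percentile 99.3 of random lists) and 0.44 with AdOVA (percentile 99.8), and limma called 0 of its 16 members, 1 adjusted over the list alone. Nfkb2, the p100 subunit gene, stood at 201 and 313 without virus and at 127 and 470 with AdOVA. Adjusted over the list alone, 1 cytokine (the granulocyte growth factor Csf3, 51.1 and 91.3, 69.6 and 192) and 1 DC maturation gene (the adhesion molecule Icam1, 617 and 1010, 815 and 1669) rose. The granulocyte markers had a median of -0.57 without virus (percentile 0.0 of random lists) and -0.17 with AdOVA. None of the 10 was called, and 3 fell when adjusted over the list alone: Elane, S100a9 (8197 and 5714, 7660 and 2618) and Camp. In the other lists the count was 0 over all probe sets and 0 adjusted over the list alone, and the medians without virus were 0.00 for interferon-stimulated genes, 0.03 for chemokines, -0.03 for uptake receptors, 0.08 for survival, -0.06 for MHC class I processing, -0.08 for proliferation, -0.06 for stress and death, 0.13 for cholesterol synthesis and 0.23 for reference genes. With AdOVA the medians of the same lists, in the same order, were 0.19, -0.24, -0.34, -0.11, 0.30 (percentile 99.6 for MHC class I processing), -0.02, -0.07, 0.03 and -0.22.

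In both pairs 20 probe sets were at least 2-fold higher and 25 at least 2-fold lower, where independent lists would share 5.3 and 5.1, and the correlation across probe sets was r = 0.23. limma called 4 as risen and 0 as fallen (1653 at an unadjusted p under 0.05), and all 4 were among the 20. The pair without virus, within fluidics round 1, had 112 higher and 157 lower, and the pair with AdOVA, which spans both rounds, had 718 and 503. No call was left in an additive fit of all 6 arrays (1426 at an unadjusted p under 0.05), which holds 1 TNFa response for all virus states. The fits with the round as a block (419) and without the AdOVA+TNFa array were additive too and also left no call. The change of model alone removed the 4 calls, so these fits do not show an effect of the round or of that array.

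**Figure D2:**
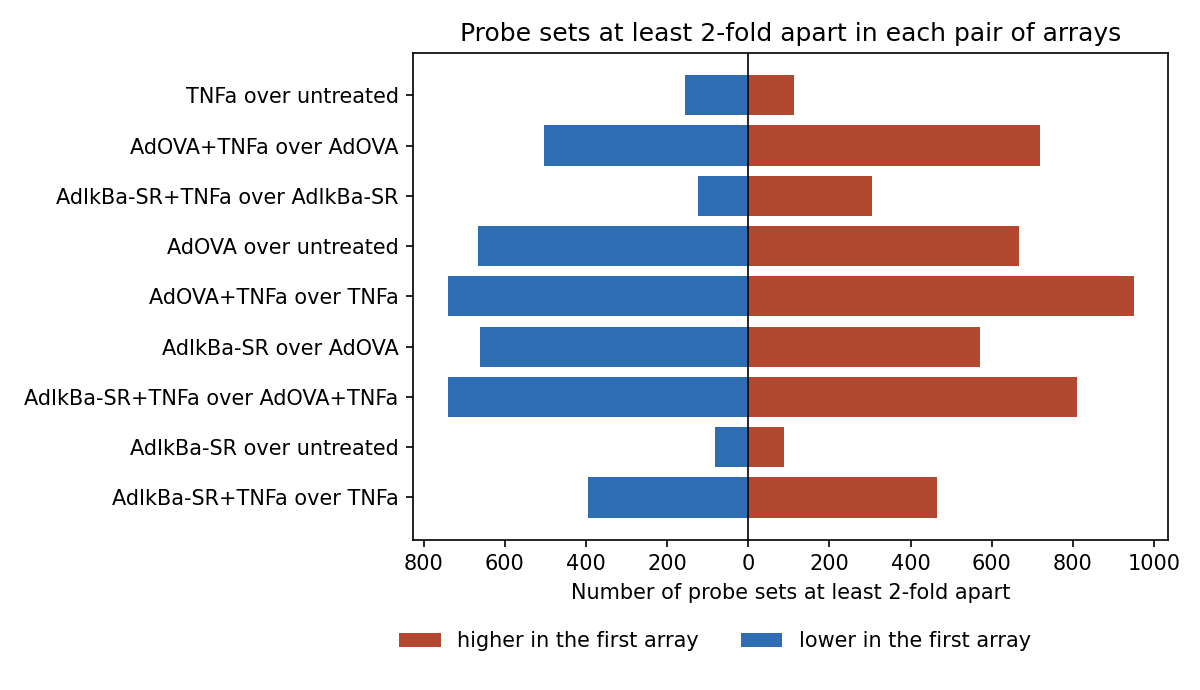
Number of probe sets at least 2-fold higher (right, red) or lower (left, blue) in each of 9 pairs of arrays, 1 bar per direction; the x axis counts probe sets. TNFa over untreated has 112 higher and 157 lower, AdOVA over untreated 666 and 665, and AdIkBa-SR over untreated 88 and 81.

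In AdIkBa-SR cells, probe sets at least 2-fold higher with TNFa without virus had a median log2 difference with TNFa of -0.00. Every TNFa response in AdIkBa-SR cells, here and below, compares arrays with different wash settings, which cannot be told apart from TNFa. Slc20a2, Stk10 and Mapk7 were named for the largest falls in response from AdOVA to AdIkBa-SR cells, so their values illustrate the choice and do not test it. Slc20a2 had signals of 52.7 and 179 without virus, 42.9 and 261 with AdOVA, and 195 and 160 with AdIkBa-SR. The kinase gene Stk10 had 77.3 and 168, then 64.4 and 184, then 147 and 151, and Mapk7, which encodes ERK5, had 76.5 and 156, 35.0 and 180, and 125 and 112. All 3 stood higher on the AdIkBa-SR array, the one with other wash settings, than on the untreated array. The called probe set of Tnfrsf1b stood at 494 and 1610 with AdIkBa-SR, 3.3-fold apart, against 2.3-fold without virus and 3.7-fold with AdOVA, and its brighter probe set at 3071 and 4449. Some members of the NF-kB pathway list were also higher with TNFa in AdIkBa-SR cells: Nfkb2 stood at 85.9 and 336, Relb at 18.2 and 158 and Tnfaip3 at 110 and 224. Others were lower, with Tank at 359 and 175 and Birc3 at 1097 and 732, and limma called none of the 16 members for TNFa in these cells.

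The comparison asks whether the super-repressor suppresses TNFa-regulated genes. The 109 probe sets at least 2-fold higher with TNFa without virus had a median log2 difference of 0.18 with AdOVA (interquartile range -0.14 to 0.72) and of -0.00 with AdIkBa-SR (-0.41 to 0.36), pairs that share no array with the choice. Of these, 20 (18.3%) were at least 2-fold higher with AdOVA and 8 (7.3%) with AdIkBa-SR. Over all probe sets with the brighter array above the floor the shares were also lower with AdIkBa-SR, 4.6% (718 of 15488) with AdOVA and 2.2% (305 of 14090) with AdIkBa-SR, so the drop from 20 to 8 does not by itself separate these genes from the rest. The median of all measured probe sets was 0.04 and 0.00. With a floor at the 60th percentile the median with AdIkBa-SR was -0.14. The 157 that were at least 2-fold lower had medians of -0.15 with AdOVA and 0.08 with AdIkBa-SR. The 10 genes with the largest fall in response from AdOVA to AdIkBa-SR cells also include Fen1, a DNA repair nuclease, Speer4f1, the telomere protein gene Terf2, Def8, Bpnt2, Zfp651 and the transcription factor gene Zeb2. For Fen1, signals were 71.6 and 51.9 with AdOVA and 427 and 57.7 with AdIkBa-SR, on a probe set that can also read other genes.

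A difference in TNFa response between AdIkBa-SR cells and the others was not called for any probe set by limma (0 calls, 737 at an unadjusted p under 0.05), and limma also called 0 for TNFa within AdIkBa-SR cells (760). Without a filter on dim probe sets these counts were 115 and 139, and with the pseudocount the second was 1. The unfiltered fit holds probe sets set to the floor on all arrays without the AdIkBa-SR virus, which have no spread of their own in it. Its prior degrees of freedom fell from 17.43 to 0.819, so its counts do not show a difference in response. The NF-kB pathway list had a median log2 difference with TNFa of 0.56 in AdIkBa-SR cells (percentile 100.0 of random lists), and 0 of its 16 members were called for the difference in response. The interferon-stimulated genes had a median of -0.28 in AdIkBa-SR cells (percentile 0.2) and 0.19 with AdOVA, and the granulocyte markers 0.17 and -0.17.

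AdIkBa-SR lowered, against AdOVA, many of the genes that AdOVA raised. Cxcl10 stood at 774 with AdIkBa-SR and 7909 with AdOVA, and at 739 and 7073 with TNFa, log2 differences of -3.35 and -3.26. The limma contrasts, fitted over all virus states, were -3.29 without and -3.32 with TNFa (SE 0.32, adjusted p = 5.6e-05 and 2.8e-05). Il6 stood at 264 and 452, log2 differences of -3.56 without and -2.61 with TNFa (fitted contrasts -3.36 and -2.80, limma adjusted p = 5.9e-05 and 0.00017). Tnfaip3 was 4.6-fold lower without TNFa and 6.5-fold lower with it, at 110 and 224 (adjusted p = 0.003 and 0.0039), and Ptgs2 5.7-fold and 5.3-fold lower, at 380 and 800. S100a4 rose to 1315 and 1219 and Cd93 to 702 and 884, 5.5-fold to 9.6-fold above the levels with AdOVA (adjusted p from 2.8e-05 to 0.001), where cells without virus had 1414 and 753, and 650 and 427.

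The comparison asks which of the genes regulated by AdOVA the super-repressor suppresses. Its pairs share the AdOVA and AdOVA+TNFa arrays with the AdOVA comparison, so chance values on those arrays move both in opposite directions. In the pair without TNFa, the other wash settings of the AdIkBa-SR array cannot be told apart from the virus. Among the 10 genes with the largest fall were also Cmpk2, Cxcl11, Gbp2, Oasl1, Mx2 and Gja1, the gap junction gene (1182 and 899 with AdOVA, 209 and 209 with AdIkBa-SR), with limma adjusted p-values of 0.0039 or less with TNFa. Genes that fell to under the floor were Pcp4, Plagl1 and Ap1m2, each called with and without TNFa, and Hdgfl3 and Zeb1, called with TNFa only, by at least 2.5-fold in each pair. Among the 10 with the largest rise, Ppbp was 7.7-fold and 13.0-fold higher, at 812 and 735 (adjusted p = 0.00045 and 0.00011). Cd36, a scavenger and fatty acid receptor, rose from 386 to 1514 and from 314 to 1136, and the complement receptor gene C5ar1 from 236 to 715 and from 353 to 1052. Fn1, Slc25a5, Eps8 and the inhibitory receptor gene Cd200r1 were called as risen with and without TNFa and Mrpl12 with TNFa only, while the mean over all probe sets gave smaller log2 differences for Fn1 (1.03), Eps8 (1.13), Olfm1 (1.22) and Cxcl11 (-1.52). Cks1b and Olfm1 rose at least 3.7-fold in each pair, and Tspan4, Cdca7l and Slc66a1, called with TNFa only, at least 2.5-fold.

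By list, 16 of 27 interferon-stimulated genes fell with TNFa and 9 without (19 and 16 adjusted over the list alone), among them Ifit2 at 1613 and 886, Gbp2 at 1605 and 1166, and Mx1 at 200 and 140. Against cells without virus their median log2 difference was 0.55 over untreated and 0.37 over TNFa, where limma called 0 and 1 of 27 as risen (6 and 3 adjusted over the list alone). Some members had lower signals than with TNFa alone, such as Ifih1 (537 and 1124) and Gbp3 (161 and 281). Of 15 cytokines, 5 fell with TNFa (Il6, Il1a, Tnf, Il12a and Il12b) and 1 without (Il6), and 7 in each state adjusted over the list alone. Of 15 chemokines, 2 fell and 2 rose with TNFa (4 and 4 adjusted over the list alone): Cxcl10 and Cxcl11 fell, and Ccl7 and Ccl17 rose. Without TNFa 3 fell, with Cxcl1 as the added one (5 fell and 2 rose adjusted over the list alone). In the NF-kB pathway list 3 of 16 fell with TNFa (Tnfaip3, Traf1 and Birc3) and 2 without (4 and 7 adjusted over the list alone). Its median was -0.82 without and -0.73 with TNFa, percentile 0.0 of random lists in both. Averaged over both pairs it was -0.63, and -0.43 when arrays had equal medians.

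Of 20 DC maturation genes, 3 fell with TNFa (Icam1, Il15ra and Fscn1, the actin-bundling protein of mature DC) and 2 without (Ccr7 and Il15ra), and 6 in each state adjusted over the list alone. Of 15 stress and death genes, 3 fell with TNFa (Hspa1a, Hspa1b and the death receptor gene Fas) and 2 without (3 and 6 adjusted over the list alone). Cd36 was the 1 uptake receptor called, in both states (1 adjusted over the list alone). limma called 0 of 9 survival, 0 of 14 MHC class I processing and 0 of 17 proliferation genes. Adjusted over the list alone, 1 survival gene fell in each state, 1 MHC class I gene fell without TNFa and 2 proliferation genes rose in each state. No cholesterol synthesis or reference gene was called in either way, with medians of -0.15 and 0.28 with TNFa.

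Granulocyte markers were higher with AdIkBa-SR than with AdOVA. With TNFa their median log2 difference was 1.12 (percentile 100.0 of random lists), and 3 of 10 rose: Prtn3 (74.8 and 219), Camp (43.0 and 202) and Ngp (1942 and 4504), or 8 adjusted over the list alone. Without TNFa the median was 0.45 and 0 of 10 rose, also adjusted over the list alone. The AdOVA+TNFa array of this pair is the one with 2601.1 on the 18S 5' probe set, against 537.0 on the AdIkBa-SR+TNFa array. The mast cell and basophil markers had medians of 0.62 without and 0.53 with TNFa, with 0 of 6 called and 2 as risen with TNFa adjusted over the list alone, and with AdOVA 1 of the 6, Cpa3, fell (545 to 275, adjusted p = 0.041, 1 adjusted over the list alone). No marker of B, NK, erythroid, macrophage or stromal cells was called in any contrast of AdOVA, TNFa or AdIkBa-SR. Adjusted over the list alone, 1 macrophage marker rose and 1 stromal marker fell for AdIkBa-SR over AdOVA with TNFa. In the same order, their median log2 differences for AdOVA over untreated were 0.38 (3 genes), 0.18 (2 genes), 0.31 (3 genes), -0.26 (5 genes) and 0.74 (3 genes), and for AdOVA+TNFa over TNFa -0.06, 0.21, 0.33, -0.18 and -0.07, with the sign turned for B and stromal markers. The 1 measured T-cell marker, Thy1, had signals of 80.1 to 185.

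**Figure D3:**
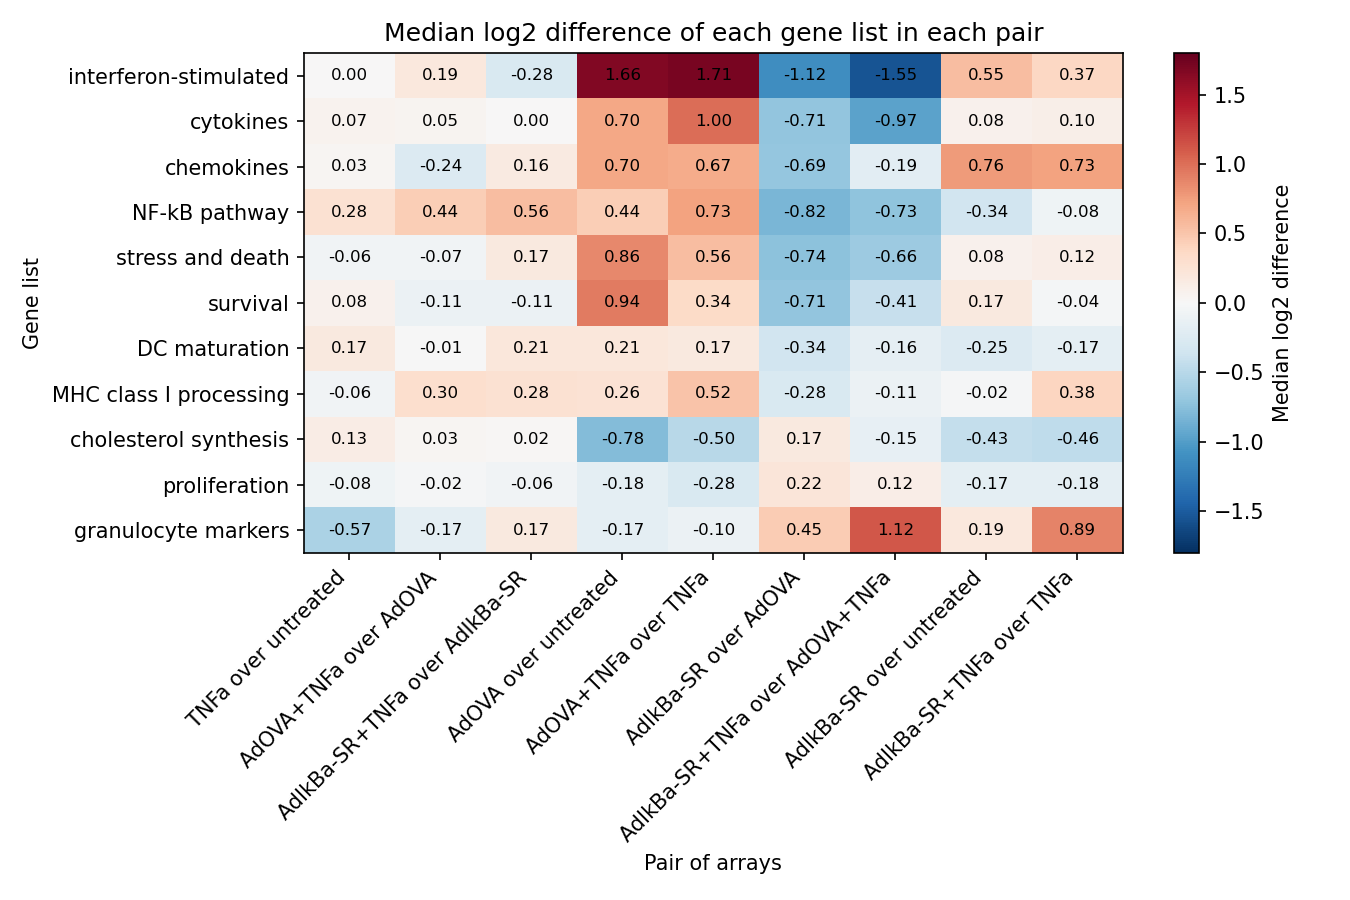
Median log2 difference of 11 gene lists (rows) in 9 pairs of arrays (columns), with red for higher, blue for lower and the value printed in each cell. Interferon-stimulated genes stand at 1.66 for AdOVA over untreated, at -1.12 for AdIkBa-SR over AdOVA and at 0.55 for AdIkBa-SR over untreated.

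Both pairs shared 168 probe sets at least 2-fold higher and 246 at least 2-fold lower with AdIkBa-SR than with AdOVA, where independent lists would share 32.0 and 32.6 (r = 0.53 across probe sets). limma called 350 as risen and 248 as fallen with TNFa (2701 at an unadjusted p under 0.05), and 65 and 109 without TNFa (2066). Ribosomal protein and respiratory chain genes were grouped after seeing the data. With TNFa, 25 of 39 and 36 of 68 of them were at least 2-fold higher and 0 at least 2-fold lower. Their median log2 differences were 1.09 and 1.07, against 0.12 and 0.23 without TNFa. The AdOVA+TNFa array, with its high ribosomal RNA signal, enters only the pair with TNFa. For these groups, that array cannot be told apart from an effect of AdIkBa-SR. With equal medians the pairs shared 331 higher and 159 lower, and limma called 256 and 83 with TNFa and 25 and 30 without. With quantile normalization the pairs shared 213 and 220, and limma called 4 and 13 with TNFa and 0 without (1635 at an unadjusted p under 0.05). The pair with TNFa lies within fluidics round 2 and had 809 higher and 740 lower, and the pair without TNFa spans both rounds, with 570 and 662. An additive fit, averaging over TNFa, called 132 and 234, and 0 with the round as a block (2014 at an unadjusted p under 0.05) or without the AdOVA+TNFa array (1956). The latter fits are not separate checks here either, since they leave the same residuals.

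How genes moved by AdOVA stood with AdIkBa-SR was also read in arrays that had no part in choosing them. No group received both viruses and no level of either virus was measured. Suppression by the super-repressor therefore cannot be told apart here from lower delivery of AdIkBa-SR. The 658 probe sets at least 2-fold higher with AdOVA without TNFa had a median log2 difference of -0.78 for AdIkBa-SR+TNFa over AdOVA+TNFa (interquartile range -1.32 to -0.38), where all measured probe sets had -0.12. Of these, 254 (38.6%) were at least 2-fold lower, and the median was -0.99 with a floor at the 60th percentile and -0.51 with a 1.5-fold threshold. For AdIkBa-SR over AdOVA without TNFa the median was -1.08, but that pair shares the AdOVA array with the choice, so chance alone puts it below 0. The other read that shares no array with the choice was weaker: the 933 probe sets at least 2-fold higher with AdOVA in the presence of TNFa had a median of -0.55 for AdIkBa-SR over AdOVA without TNFa, and 247 (26.5%) were at least 2-fold lower. The read of the 658 uses the AdOVA+TNFa array, with 2601.1 on the 18S 5' probe set. The 665 probe sets at least 2-fold lower with AdOVA without TNFa had a median of 0.62 for AdIkBa-SR+TNFa over AdOVA+TNFa, and 178 (26.8%) were at least 2-fold higher.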

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

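The arrays carry control probe sets for mouse 18S ribosomal RNA, which enter none of the comparisons, and they read far more signal on some arrays than on the untreated one. The tests in this part were chosen after the data had been seen. The 5' probe set read 2601.1 on the AdOVA+TNFa array, 21.6 times the 120.3 of the untreated array, and 537.0 on the AdIkBa-SR+TNFa array, 4.5 times that level. The 3' probe set read 1061.3 on the AdOVA+TNFa array, 4.6 times the untreated 229.4, and the middle probe set 302.6, 4.4 times the untreated 68.6. What drew attention to them is a level at least 4 times that of the untreated array, in data outside the main measurement. On the other arrays the 5' probe set read 176.2 with TNFa, 233.6 with AdOVA and 340.4 with AdIkBa-SR. The ratio of 3' to 5' signal for actin, a measure of RNA integrity, was 1.38 on the AdOVA+TNFa array and 1.09 on the AdIkBa-SR+TNFa array, within or below the 1.36 to 1.84 of the arrays without TNFa. With 1 array per group, no cause of these levels was tested.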

How the results depend on the processing

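Of the counts and medians that answer a comparison, 75 values moved under the settings tried, 53 towards 0 and 22 away from it, and 39 did not move beyond their spread or 1.5 times their count. The fits with fluidics round as a block and without the AdOVA+TNFa or the AdIkBa-SR array were chosen after seeing the data. Where no other reason is given, the cause was not tested. The balance of directions turned with scaling: equal medians gave more lower than higher probe sets for AdOVA and more higher than lower for AdIkBa-SR over AdOVA, and with quantile normalization limma called 4 and 13 in place of 350 and 248 for AdIkBa-SR over AdOVA with TNFa. By construction, a higher fold threshold counts fewer probe sets and a lower one more. MAS5 signals near the floor limit all of these, since 14906 of 22626 probe sets were measured.

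Probe sets at least 2-fold apart in both pairs numbered as follows. For TNFa, against 20 higher and 25 lower, the counts were 74 and 70 with the 25th percentile as the floor, 6 and 7 with the 60th, 10 and 6 with the pseudocount, 244 and 351 at 1.5-fold, and 3 and 0 at 3-fold. For AdOVA, against 285 and 204, they were 456 and 311 with the 25th percentile floor, 182 and 113 with the pseudocount, 981 and 904 at 1.5-fold, and 79 and 30 at 3-fold, with 109 lower at the 60th percentile floor and 336 lower with equal medians. For AdIkBa-SR over AdOVA, against 168 and 246, they were 331 and 159 with equal medians, 88 and 156 with the 60th percentile floor, 87 and 159 with the pseudocount, 741 and 979 at 1.5-fold, and 20 and 57 at 3-fold, with 434 lower at the 25th percentile floor.

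The median TNFa response in AdIkBa-SR cells of genes higher with TNFa without virus was -0.00, at most 0.02 under any setting, and -0.14 with the 60th percentile floor, -0.09 at 1.5-fold and -0.22 at 3-fold. For genes higher with AdOVA, the median of AdIkBa-SR+TNFa over AdOVA+TNFa was -0.78. It was -0.68 with equal medians, -0.64 with the 25th and -0.99 with the 60th percentile floor, -0.89 with the pseudocount, -0.51 at 1.5-fold and -1.59 at 3-fold.

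The 4 limma calls for TNFa became 16 with the pseudocount and 0 under 10 other settings. Those settings, with the counts at an unadjusted p under 0.05, were no trend (1601), no filter (1052), without probe sets that can read several genes (1302), the additive fit of 6 arrays (1426), the round as a block (419), without the AdOVA+TNFa array (416), equal medians (1468), quantile normalization (1372) and the 25th (1588) and 60th (1126) percentile floors. The fits with the round as a block and without the AdOVA+TNFa array were additive, and the additive fit of 6 arrays already gave 0. The additive fit of 4 arrays gave 4 and the fit without the AdIkBa-SR array 3.

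For AdOVA, limma's 1175 calls became 765 without probe sets that can read several genes, 492 in the additive fit of 6 arrays, 259 with quantile normalization, 239 with the 25th and 605 with the 60th percentile floor. They became 0 without a filter (2185 at an unadjusted p under 0.05), and stayed at 1200 in the additive fit of 4 arrays and 1193 without the AdIkBa-SR array. The 492 of the additive fit became 0 with the round as a block (2042), and no call was left without the AdOVA+TNFa array. The prior degrees of freedom of eBayes fell from 6.934 in the additive fit to 1.617 and 1.637, so these fits also had less power. They leave the same residuals and so are not separate checks of the round and of that array. For AdIkBa-SR over AdOVA, the 598 calls with TNFa and 174 without became 264 and 97 without the trend, 390 and 77 without probe sets that can read several genes, 339 and 55 with equal medians, and 203 and 53 with the 60th percentile floor. With no filter they were 59 and 0 (1623 at an unadjusted p under 0.05), with quantile normalization 17 and 0 (1635), with the 25th percentile floor 9 and 0 (2136), and with the pseudocount 309 without TNFa. The difference in TNFa response went from 0 calls (737 at an unadjusted p under 0.05) to 115 without a filter, and TNFa within AdIkBa-SR cells from 0 (760) to 139 without a filter and 1 with the pseudocount. Without the filter, probe sets set to the floor on all arrays without the AdIkBa-SR virus have no spread of their own. The 115 and 139, and the 59 above, therefore do not show an effect.

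Among values for named genes under other settings, 439 stayed within the gene's standard error and 124 moved beyond it, 101 towards 0 and 23 away from it, and none of the 124 changed sign. Among list medians, 107 stayed within their spread and 12 moved beyond it, 8 towards 0 and 4 away. These medians are over each gene's average of both pairs. For the proliferation list in AdIkBa-SR over AdOVA this gave -0.02, although the medians of the single pairs were 0.22 without and 0.12 with TNFa, and it changed sign in 4 of the 107. For AdIkBa-SR over untreated cells, a comparison added after seeing the data, the additive fit called 1 probe set (630 at an unadjusted p under 0.05) and called 0 with the round as a block (818) or without the AdOVA+TNFa array (531).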

Other observations

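AdIkBa-SR cells were also compared with cells without virus, a comparison chosen after seeing the data, as were the genes named in it, the search for genes beyond both other states, the ribosomal and respiratory chain groups and the tests that weigh explanations. The NF-kB pathway list, its place among random lists and limma's test of the difference in TNFa response were planned. Mmp13, a collagenase, rose from signals of 777 untreated and 575 with TNFa to 4301 and 3828 with AdIkBa-SR (limma adjusted p = 0.0054 without and 0.0042 with TNFa), above its 2688 and 2886 with AdOVA. Ccl7, a monocyte chemokine, rose from 405 and 437 to 2608 and 2221 (adjusted p = 0.031 and 0.0044), and had 1550 and 694 with AdOVA. The monocyte chemokine Ccl2 had 13259 and 13014 with AdIkBa-SR, 5977 and 5162 without virus, and 9689 and 5536 with AdOVA. With TNFa, limma also called Cxcl1, Oasl1, Metrnl, Npy, Rnasek and 1 of 5 measured probe sets of Malat1 as risen, and as fallen a probe set of Fen1 that can also read other genes. The chemokine list stood at a median log2 difference of 0.76 without and 0.73 with TNFa (percentile 100.0 of random lists in both), the interferon-stimulated genes at 0.55 and 0.37, and the granulocyte markers at 0.19 and 0.89. In total, limma called 11 as risen and 1 as fallen with TNFa (1455 at an unadjusted p under 0.05) and 2 as risen without TNFa (357). With TNFa no call was left with equal medians (1295 at an unadjusted p under 0.05), quantile normalization (1098), the 25th percentile floor (1333) or no trend (1389), and none without TNFa under the same settings (376, 308, 456 and 356). Calls with TNFa numbered 59 without a filter, where probe sets at the floor on all arrays without the AdIkBa-SR virus have no spread of their own. They numbered 19 with the pseudocount, 3 without probe sets that can read several genes and 2 with the 60th percentile floor. Without TNFa these were 0, 2, 1 and 0.

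Some genes had signals beyond both other virus states on the AdIkBa-SR arrays, with and without TNFa. Against cells without virus, limma called no probe set of Jak2, Fas, Lgmn or Emp1 in either TNFa state. Jak2, a cytokine receptor kinase, had 873 and 770 with AdIkBa-SR on its brighter probe set, against 1140 and 2032 without virus and 1566 and 1742 with AdOVA, and 527 and 560 on the other, against 830 and 1704 and then 1263 and 1640. The death receptor gene Fas had 52.6, which is under the floor, and 61.5, against 122 and 233 and then 221 and 193. Higher than in both were the lysosomal protease gene Lgmn (1746 and 1621, against 974 and 1074 and then 485 and 584) and Emp1 (334 and 422, against 134 and 120 and then 116 and 148). By at least 1.5-fold, 29 probe sets lay above both other states and 23 below, where 50 simulated sets of unchanged arrays gave means of 13.3 and 10.76 and at most 24 and 21. The simulated arrays carried no AdOVA effect. Where AdOVA moves a gene the other way, only the arrays without virus have to be passed. The simulated counts can therefore be too low for chance, and they do not show an excess. These differences have no replicate check.

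On the whole, the AdIkBa-SR arrays lay nearer to the arrays without virus than the AdOVA arrays did. Without TNFa, 169 probe sets were at least 2-fold apart between AdIkBa-SR and untreated and 1331 between AdOVA and untreated, and with TNFa these counts were 859 and 1691. Fluidics round is argued against as the cause, since AdOVA and untreated shared a round and still differed in 1331. The count of 1691 uses the AdOVA+TNFa array, with 2601.1 on the 18S 5' probe set, and that array could by itself raise it. The pair with TNFa, with 859, does not use the AdIkBa-SR array, so the other wash settings of that array could not act on it. For the pair without TNFa, those settings cannot be told apart from the virus, since 1 array carries both, and the count of 169 bounds only what they added. Lower delivery of AdIkBa-SR also stays open, since the NF-kB pathway list stood at -0.08 with TNFa and -0.34 without against cells without virus and no level of either virus was measured, and blockade of NF-kB by the super-repressor may be the cause as an untested hypothesis.

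Ribosomal protein and respiratory chain genes, groups chosen by symbol after seeing the data, were lower with TNFa without virus (medians -0.49 over 39 genes and -0.55 over 68) and with AdOVA, with 2 of 39 and 2 of 68 at least 2-fold lower without virus and 19 and 29 with AdOVA, while the medians with AdIkBa-SR were -0.00 and -0.03. Scaling is argued against, since the median nearest to 0 over both groups, both pairs and 3 scalings was -0.47. Higher ribosomal RNA on the AdOVA+TNFa array could not act on the pair without virus, which does not use that array and had a median nearest to 0 of -0.49. For the AdOVA pair (median nearest to 0 of -0.87) it cannot be told apart from TNFa, since 1 array carries both. Differences between arrays that have nothing to do with TNFa stay open, since AdOVA over untreated had -0.43 in the respiratory chain group, and so does the RNA composition of the TNFa array, which read more 18S than the untreated array on all 3 probe sets (176.2 against 120.3, 115.4 against 68.6 and 373.2 against 229.4). Granulocyte markers moved alongside, with -0.57 for TNFa without virus, -0.17 with AdOVA and 0.17 with AdIkBa-SR, so that neither a change in cell types nor a response to TNFa that AdIkBa-SR prevents, which may account for it, was tested.

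NF-kB pathway genes were higher with TNFa in AdIkBa-SR cells, by a median log2 difference of 0.56. A shift of the AdIkBa-SR array that depends on signal is argued against, since the median lay at percentile 100.0 of random lists matched on signal. The other wash settings of the AdIkBa-SR array cannot be told apart from TNFa in this pair. Cells that the AdIkBa-SR virus did not block could raise the list too. This cannot be told apart from a response in blocked cells, since whole cultures were measured. The 0.56 lies above the 0.28 without virus and 0.44 with AdOVA that unblocked cultures gave. Whether these medians differ was not tested: the bootstrap SD of 0.29 for the 0.56 is over genes and does not measure how far arrays vary. The list's members went both ways, with 4 at least 2-fold higher and 1 at least 2-fold lower, and limma called 0 of the 16 for the difference in response between AdIkBa-SR cells and the others, also when adjusted over the list alone. TNFa signals that reach these genes despite the super-repressor are a biological hypothesis that was not tested.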
